A study of Mus musculus with 64 samples.

How the data were processed

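Total RNA from adipose tissue of mice was measured by sequencing in 64 libraries of 15 groups. The tissues were inguinal fat (iWAT, a subcutaneous depot), epididymal fat (eWAT, a visceral depot) and brown fat (BAT). The mice were C57BL/6J (B6 below), 129S1/SvlmJ (129 below) or the B6/129S1 F1 hybrid (F1 below), on a low-fat diet (LFD) or a high-fat diet (HFD). Some groups were given rosiglitazone (rosi), a drug that activates the nuclear receptor PPAR gamma, and the labels call the untreated groups control. Each library was placed in its group by the strain, tissue, diet and agent of its labels, and 0 libraries were left without a group. Per the labels, RNA was taken with Trizol and RNeasy columns, ribosomal RNA was removed with Ribo-Zero gold, and libraries were made with TruSeq kits. The labels also name 7 sequencing runs and lanes, given here in words where they mattered.

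The deposited files held raw read counts per gene symbol, 1 library per file, with 24328 genes and 5 tallies of reads that were not assigned to a gene. Per the labels, the authors aligned reads to mm9 with TopHat2 version 2.1.0 and counted them with HTSeq. The strand setting, the gene annotation and any read filter were not stated, so antisense reads and reads shared between paralogs could not be told apart from the counts of a gene. The mm9 build comes from C57BL/6J, so reads of the other alleles were aligned to a B6 sequence. Tallies were kept out of library sizes and tests. Reads in no gene feature made up 29.3 to 70.6% of the reads in a gene, in no feature or in more than 1 gene, and ambiguous reads made up 0.195 to 1.23%. No genomic positions are given, since the annotation at hand was of another build.

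Totals over genes ran from 3099737 to 9551251 counts per library. A floor of 3 counts over a group stood for a gene with no counts in that group, and folds against such a group are given as bounds only. Counts are of reads, not of molecules, so floors cover counting error only. CPM, the count of a gene relative to the size of its library, used sizes scaled by TMM over all 64 libraries, and values per library on a log scale are log2(CPM + 1). CPM are given as mean ± SD, and log2 fold changes as value ± SE from the fitted model.

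For each of 16 comparisons, genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest, 2-sided) in R 4.3.3. The libraries of the compared groups alone entered the fit, with TMM scaling and the filter of filterByExpr (minimum count 10, minimum total 15). Adjusted p is Benjamini-Hochberg over the genes tested, and genes under 0.05 are said to rise, fall or change. Differences between 2 strains or 2 depots in the effect of rosi or diet were tested as interaction terms over 4 groups. Every p of a gene is from edgeR unless another tool is named beside it. Most groups held 4 libraries, and the first set of B6 eWAT and the F1 groups held 5 each. The labels do not say that replicates are separate animals, so p-values measure the spread between samples, which may be technical in part. Run or lane went with the groups in 5 comparisons and could not be told apart from them there: diet in the second set of B6 eWAT, diet in 129 eWAT, strain in control iWAT, strain in rosi iWAT, and BAT against iWAT. The interaction of diet with strain in eWAT compares 2 such differences that crossed the same runs.

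Gene lists (22) were fixed before the data were examined: thermogenic brown fat genes (35 members in the files), beige fat selective markers (14), oxidative phosphorylation (52), tricarboxylic acid cycle (18), fatty acid oxidation (23), PPAR gamma target and lipid storage genes (31), de novo lipogenesis (16), adipocyte secreted factors (18), creatine, calcium and glycerol cycling (11), collagen and matrix (22), proliferation (18), interferon response (18), circadian clock (15) and developmental depot genes (17), and markers of macrophages (25), lymph node B and T cells (20), skeletal muscle (18), epithelium (15), epididymis and testis (18), mesothelium (9), endothelium (15), and nerve and Schwann cells (13). Some genes stand on more than 1 list. Each list with at least 3 tested genes was compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over all 320 tests. Of these, 151 passed with the preset correlation and 0 with an estimated correlation, where 40 had an unadjusted p under 0.05. A list's call therefore rests on the preset value, and its adjusted p with an estimated correlation is given beside it. Counts of list members are over all genes tested, with counts adjusted over the list alone beside them, or with no second count where a list passed and the counts were equal.

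The genes named in each comparison followed a rule: Ucp1, Nnt in strain comparisons (known to be deleted in part in C57BL/6J), the list members with the lowest adjusted p, and up to 5 genes each way with the largest fold change, a mean of at least 5 CPM and no overlap between the groups. Interactions named up to 5 each way by adjusted p. Genes outside the rule are marked as chosen after their values were seen. Of 923 named results that passed the test, 816 also passed without any 1 library, and the text says so for each named gene where this did not hold.

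Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma voom with sample quality weights, 1 fit over all libraries of the tissue, the replicate number of the labels as a block, an absolute log2 fold change of at least 1, and leaving out each library in turn. A covariate of muscle markers, and a gene set without genes that follow muscle markers, were added after seeing the data. The replicate numbers were checked for pairing by the correlation of residuals between libraries of equal number. In BAT against iWAT all 4 of 4 pairs correlated (r 0.223 to 0.334), and in no other comparison did every checked pair correlate by more than 0.1. For interactions, the check paired rosi with control, or HFD with LFD, within a strain or depot. Libraries of eWAT and iWAT of equal number were therefore not checked against each other. The test procedure was checked on simulated counts with 200 changed genes. At a true change of 2-fold, edgeR recovered 74.6% in a set like B6 iWAT, 77.6% in one like 129 iWAT and 37.3% in one like B6 eWAT. Genes were simulated independently of each other, without shifts of whole libraries. Recovery and false calls given here and below therefore need not hold for the real sets. Pairs of libraries of the same group were compared for duplication, and the lowest of 106 dispersion statistics was 2.51, where repeat sequencing of 1 library would give a value near 1. Some single-gene results are not reported here.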

Results

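Gene expression was measured in inguinal, epididymal and brown fat of C57BL/6J (B6), 129S1/SvlmJ (129) and B6/129S1 F1 hybrid (F1) mice. B6 iWAT was sampled on LFD control (n = 4), HFD control (n = 4) and HFD with rosi (n = 4), and 129 iWAT on HFD control (n = 4) and HFD with rosi (n = 4). F1 iWAT was sampled on LFD control (n = 5) and LFD with rosi (n = 5). B6 eWAT came as a first set with no agent named, on LFD (n = 5) and HFD (n = 5), and as a second set of LFD control, HFD control and HFD with rosi (n = 4 each). 129 eWAT was sampled on LFD control and HFD control (n = 4 each), and B6 BAT on HFD with no agent named (n = 4). Totals over genes ran from 3099737 to 9551251 counts per library, and 15030 to 21330 genes had at least 1 count.

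Ucp1, which encodes the uncoupling protein of brown fat and is the gene the series title names, spanned a wide range. It averaged 5680 ± 773 CPM in B6 BAT and 0.780 ± 0.566 CPM in B6 iWAT on HFD. In iWAT of HFD mice given rosi, it was at 18.8 ± 12.8 CPM in B6 and 80.1 ± 37.2 CPM in 129, and in F1 given rosi on LFD it was at 2438 ± 1618 CPM. Single libraries stood apart in both control groups of 4 with the highest spread: 171 CPM in 129 iWAT HFD control replicate 3 and 154 CPM in B6 iWAT LFD control replicate 3.

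**Figure D1:**
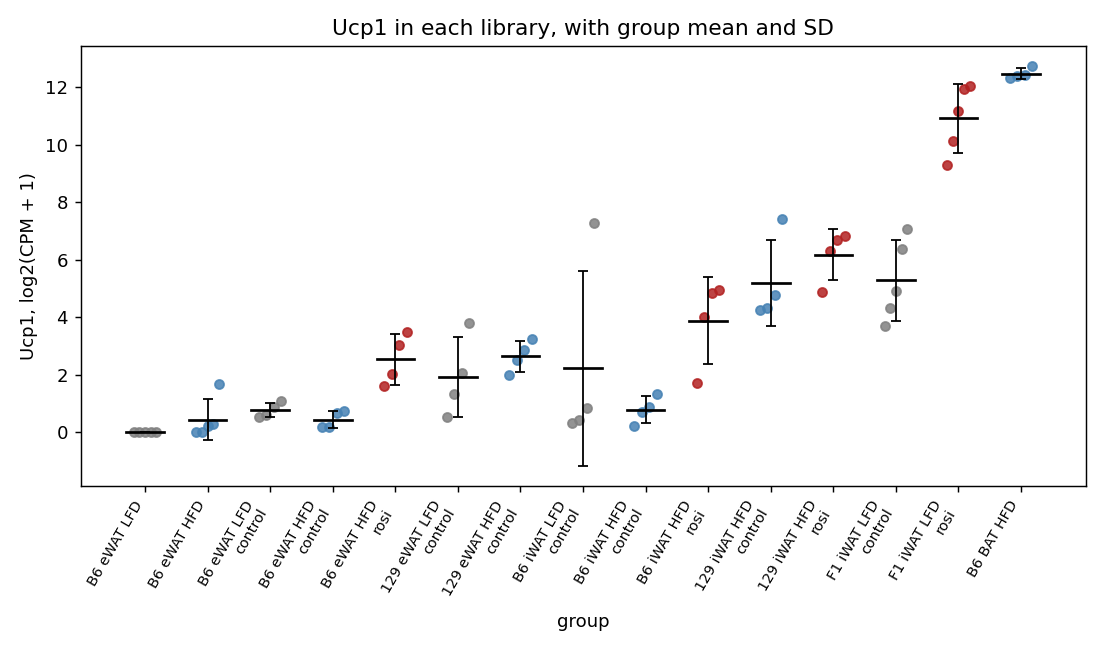
Ucp1 in log2(CPM + 1) for each of the 15 groups on the x axis, with a point per library, a black bar at the group mean and an error bar of 1 SD (rosi groups red, other LFD groups grey, other HFD groups blue). B6 BAT averaged 5680 CPM, F1 iWAT with rosi 2438 CPM, B6 iWAT with rosi 18.8 CPM and B6 iWAT HFD control 0.780 CPM.

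The first question was what rosi did in iWAT of B6 mice on HFD, the depot and strain of the series title (4 rosi against 4 control libraries). Ucp1 rose by 4.59 ± 0.76 on the log2 scale (adjusted p = 0.0037, and 0.0707 in a fit over all iWAT libraries). Among 12789 genes tested, 873 rose and 816 fell. Among genes that rose was Sptlc3, a subunit of the enzyme that starts sphingolipid synthesis, from 0.620 ± 0.171 to 53.0 ± 10.6 CPM (log2 6.39 ± 0.23, adjusted p = 4.9e-07). Elovl3, a fatty acid elongase of brown fat, rose from 2.41 ± 1.84 to 61.0 ± 26.1 CPM (log2 4.63 ± 0.44, adjusted p = 0.00021). Chrna2, a nicotinic receptor subunit, rose from 3.78 to 33.7 CPM (log2 3.13 ± 0.22). Genes that fell included Saa3, an acute-phase apolipoprotein (12.0 to 0.359 CPM, log2 -5.03 ± 0.61), and the protease inhibitor Serpina3n (476 ± 67.6 to 65.8 ± 22.4 CPM, log2 -2.87 ± 0.22, adjusted p = 6.3e-05). Reads of Serpina3n may be shared with its paralogs. Wfdc21, Tph2 and Trabd2b fell too, at log2 -2.83 ± 0.37, -2.73 ± 0.41 and -2.71 ± 0.16.

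Genes of mitochondrial fuel use rose together. Of 52 oxidative phosphorylation genes, 50 rose and 0 fell (51 and 0 adjusted over the list alone), with a median of log2 0.75 (camera adjusted p = 5.41e-50, adjusted p = 0.303 with an estimated correlation). Cox7b stood at 1.04 ± 0.12 and Ndufb5 at 0.80 ± 0.09. All 18 tricarboxylic acid cycle genes rose (18 adjusted over the list alone; adjusted p = 4.46e-27, adjusted p = 0.303 with an estimated correlation). Of 23 fatty acid oxidation genes, 21 rose and 1 fell, in both counts, with Hadhb going from 526 ± 46.1 to 1337 ± 210 CPM (adjusted p = 1.13e-36, adjusted p = 0.259 with an estimated correlation). Of 28 thermogenic genes tested, 14 rose and 3 fell (19 and 3 adjusted over the list alone, adjusted p = 6.5e-09, adjusted p = 0.413 with an estimated correlation). Cox7a1 rose by log2 1.94 ± 0.26 and Pdk4, which restrains pyruvate oxidation, by 1.38 ± 0.15. On the way from iWAT to the level of BAT, the 27 thermogenic genes higher in BAT and tested in both comparisons covered a median of 17.8% of the log2 distance, from -48.3% for P2rx5 to 120.3% for Elovl3, with 20 above 0. The rosi change and the distance to BAT were taken from the same HFD control libraries, so errors in the control values enter both. Genes with too few counts in the rosi comparison have no such share, among them Kng2 and Cpn2, at 0.0912 and 0.466 CPM with rosi against 274 and 113 CPM in BAT. Ucp1 with rosi stood at 0.330% of its CPM in BAT.

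Lipid storage genes rose in part. Of 31 PPAR gamma target genes, 14 rose and 0 fell (15 and 1 adjusted over the list alone, adjusted p = 1.7e-11, adjusted p = 0.413 with an estimated correlation). Acaa1b rose by log2 1.82 ± 0.13, the triglyceride lipase Pnpla2 by 1.29 ± 0.11 and Gpd1 by 1.35 ± 0.18. In de novo lipogenesis, 5 of 16 rose and 1 fell (6 and 2 adjusted over the list alone, adjusted p = 0.00901, adjusted p = 0.53 with an estimated correlation). Acacb and Acaca, which make malonyl-CoA, rose by 1.22 ± 0.10 and 0.82 ± 0.12, and Elovl6 fell by 1.12 ± 0.22. Of 17 secreted factors, 4 fell and 0 rose (5 and 0 adjusted over the list alone), among them Cfd, the protease adipsin, from 949 ± 553 to 272 ± 58.3 CPM (adjusted p = 0.0345, adjusted p = 0.413 with an estimated correlation). Beige markers had 3 of 8 higher and 1 lower (3 and 3 adjusted over the list alone). The fatty acid transporter Slc27a1 rose from 392 ± 48.0 to 907 ± 148 CPM. The list's median was log2 -0.12 while their mean was 0.26 and the test pointed up (adjusted p = 0.102).

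Of 15 endothelial markers, 9 fell and 0 rose (11 adjusted over the list alone, adjusted p = 1.06e-07, adjusted p = 0.361 with an estimated correlation). The receptor Tie1 fell from 80.2 ± 7.71 to 40.5 ± 5.08 CPM, and Pecam1 was at log2 -0.59 ± 0.11. Of 22 matrix genes, 4 fell and 0 rose (5 adjusted over the list alone), Sparc at -0.54 ± 0.12 (adjusted p = 0.00729, adjusted p = 0.706 with an estimated correlation). Among 14 clock genes, 4 fell and 0 rose (9 and 1 adjusted over the list alone), Dbp at -0.79 ± 0.14 (adjusted p = 0.00323, adjusted p = 0.413 with an estimated correlation). No call was made for the lists of macrophages (0 of 24 members called, adjusted p = 0.808), skeletal muscle (0 of 13, adjusted p = 0.805) or lymph node cells (0 of 5, adjusted p = 0.635). The same held for proliferation (adjusted p = 0.274), interferon response (adjusted p = 0.228), creatine and glycerol cycling (adjusted p = 0.568) or depot genes (adjusted p = 0.536). The nerve list had a median of 0.03 and a mean of -0.14 (adjusted p = 0.183), with Scn7a at -0.85 ± 0.10 and S100b at -1.46 ± 0.22 past the test. The single epithelial gene tested, Trp63, fell by 3.10 ± 0.46. No epididymis or testis gene passed the count filter in any of the 16 comparisons. Without rosi replicate 1 the calls changed to pass for proliferation (adjusted p = 0.000762), nerve (0.0337) and interferon (0.0331) and to miss for secreted factors (0.0866). The latter also missed without rosi replicate 4 (0.0559), where muscle passed (0.00087), and matrix genes missed without rosi replicate 3 (0.0551). The count of 1689 genes became 929 without rosi replicate 4, 1066 without control replicate 4 and 2542 without rosi replicate 1.

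In 129 iWAT on HFD, the same contrast (4 against 4) gave 5 genes higher and 9 lower among 12703. Arxes2 and Arxes1, paralogs expressed in adipocytes that may share reads, rose by 1.15 ± 0.15 and 1.12 ± 0.15 (adjusted p = 0.019 each), and Svep1 went from 207 to 353 CPM. Sycp3 and Abcg1, a cholesterol exporter, rose by 1.02 ± 0.15 and 0.62 ± 0.09. Cmklr1, the chemerin receptor, fell from 137 ± 16.1 to 63.7 ± 10.1 CPM (log2 -1.12 ± 0.13, adjusted p = 0.019). Orm3, S100b, Trabd2b and Anxa8 fell by log2 values of -2.61 ± 0.34, -1.39 ± 0.21, -1.28 ± 0.16 and -1.21 ± 0.16. Ucp1 did not pass the test (80.1 ± 37.2 against 58.5 ± 74.9 CPM, log2 0.43 ± 0.71, adjusted p = 0.935), and without control replicate 3 it was at 1.93 (adjusted p = 0.122). Each of these 14 calls, the 10 named among them, was lost without control replicate 1, 2 or 4 or rosi replicate 2 or 3, which left 0 genes by edgeR, while 23 were called without control replicate 3 and 40 without rosi replicate 4. At an unadjusted p under 0.05 there were 1084 genes. DESeq2 called 193, limma voom with quality weights 26, and a fit over all iWAT libraries 29.

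As lists, fuel genes of 129 iWAT were also higher with rosi, though no member passed over all genes. The median was log2 0.23 for oxidative phosphorylation (adjusted p = 3.93e-09, adjusted p = 0.595 with an estimated correlation), 0.28 for the tricarboxylic acid cycle (adjusted p = 1.9e-05, adjusted p = 0.593 with an estimated correlation) and 0.31 for fatty acid oxidation (adjusted p = 6.04e-08, adjusted p = 0.468 with an estimated correlation). PPAR gamma target genes had a median of 0.30, with 12 of 31 higher and 1 lower adjusted over the list alone (adjusted p = 1.04e-07, adjusted p = 0.421 with an estimated correlation). Thermogenic genes had a median of -0.05 (adjusted p = 0.852; 3 higher and 3 lower adjusted over the list alone), and Elovl3 was at 2.90 ± 0.58 (adjusted p = 0.13). Without control replicate 3, the thermogenic list passed (adjusted p = 0.0021), as did muscle markers (1.67e-13), and nerve markers missed (0.0636). Interferon genes had a median of -0.32 (adjusted p = 6.44e-05, adjusted p = 0.455 with an estimated correlation) and nerve markers of -0.35 (adjusted p = 0.00212, adjusted p = 0.53 with an estimated correlation). Muscle markers took 0.00827 to 3.06% of counts in the control libraries and 0.00534 to 0.814% in the rosi libraries, and their median of -1.46 and mean of -0.70 differed in sign from the test (adjusted p = 0.347).

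F1 mice carry 1 allele of each strain, and the contrast in their iWAT was made on LFD (5 against 5). Ucp1 rose from 55.1 ± 51.9 to 2438 ± 1618 CPM (log2 5.45 ± 0.74, adjusted p = 9.2e-05). Rosi raised 2217 and lowered 2266 of 11859 genes. Elovl3 rose from 0.787 ± 0.975 to 196 ± 121 CPM (log2 7.85 ± 0.70, adjusted p = 4.4e-06), the fatty acid binding protein Fabp3 from 1.61 to 156 CPM (log2 6.51 ± 0.85) and Gyk, glycerol kinase, from 21.5 to 241 CPM (log2 3.48 ± 0.40). Among genes that fell were Cyp2f2, a cytochrome P450 (28.5 to 0.510 CPM, log2 -5.75 ± 0.33, adjusted p = 3.7e-07), Folh1 (-4.07 ± 0.39), Orm3 (-3.93 ± 0.35), Cmklr1 (155 ± 34.7 to 13.1 ± 3.65 CPM) and Ripk4 (-3.37 ± 0.30).

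Of 30 thermogenic genes in F1 iWAT, 25 rose and 0 fell (26 adjusted over the list alone), with a median of log2 1.81 (adjusted p = 3.09e-17, adjusted p = 0.361 with an estimated correlation). Cox8b went from 107 ± 31.4 to 559 ± 111 CPM, and the proton channel gene Otop1 rose by 2.60 ± 0.21. Oxidative phosphorylation had 50 of 52 higher, Cyc1 from 134 to 451 CPM (adjusted p = 4.21e-51, adjusted p = 0.259 with an estimated correlation). The tricarboxylic acid cycle had 17 of 18 higher (18 adjusted over the list alone; adjusted p = 1.71e-26, adjusted p = 0.259 with an estimated correlation). Fatty acid oxidation had 21 of 23 higher (22 adjusted over the list alone), with the carnitine carrier Slc25a20 at 2.20 ± 0.15 (adjusted p = 3.02e-38, adjusted p = 0.259 with an estimated correlation). PPAR gamma targets had 15 of 31 higher and 2 lower (adjusted p = 2.94e-07, adjusted p = 0.468 with an estimated correlation). Of 17 secreted factors, 10 fell and 0 rose (12 adjusted over the list alone), the imprinted gene Nnat from 1005 to 176 CPM (adjusted p = 2.58e-05, adjusted p = 0.259 with an estimated correlation). Beige markers had 2 of 7 higher and 3 lower, a median of -0.28 and a mean of 0.05 (adjusted p = 0.741).

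Macrophage markers fell in F1 iWAT: 15 of 17 fell and 0 rose (17 adjusted over the list alone, adjusted p = 2.31e-06, adjusted p = 0.455 with an estimated correlation). The scavenger receptor Cd163 fell from 115 ± 39.8 to 27.4 ± 9.09 CPM and Trem2 from 7.32 to 1.24 CPM. Matrix genes had 12 of 21 lower and 1 higher (14 and 1 adjusted over the list alone), Dcn, the proteoglycan decorin, from 506 to 137 CPM (adjusted p = 3.99e-05, adjusted p = 0.449 with an estimated correlation). Clock genes had 10 of 14 lower and 2 higher, Dbp from 90.1 to 27.3 CPM and Per2 at -1.51 ± 0.18 (adjusted p = 6.67e-05, adjusted p = 0.413 with an estimated correlation). Interferon genes had 4 of 15 lower, Irf7 at -1.35 ± 0.17 (adjusted p = 0.00845, adjusted p = 0.53 with an estimated correlation). The endothelial list had 3 of 15 higher, with a median of -0.01, a mean of 0.09 and no call (adjusted p = 0.648). Cr2, a B cell marker, was at 2.54 against 24.6 ± 47.5 CPM, a call that held in 4 of 10 leave-one-out fits. The libraries of F1 iWAT had the highest share of reads in no gene feature, 66.8 to 70.6%, in both groups alike.

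Genes called in B6 iWAT overlapped with those of the other iWAT contrasts more than independent draws would (one-sided tests). With 129 they shared 5 higher genes against 0.348 under independence (Fisher exact p = 1.6e-06) and 8 lower against 0.513 (p = 2.8e-10). With F1 they shared 713 higher against 160 and 454 lower against 146 (Fisher exact p = 5.3e-146 for the lower genes), and 4 and 12 genes were called in opposite directions. Genes are not independent draws, so these p-values do not measure replication across samples. The 129 calls were also lost in some fits without 1 library, as given above. Across genes, which are not independent replicates, log2 fold changes of B6 iWAT correlated with those of 129 (Pearson 0.43, Spearman 0.43), F1 (0.65, 0.64) and B6 eWAT (0.56, 0.49), pairs chosen after seeing the data.

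In B6 eWAT on HFD (4 against 4, 1 lane), edgeR called 0 of 13213 genes for rosi, with 624 at an unadjusted p under 0.05. DESeq2 called 32 and limma voom with quality weights 32. Ucp1 was at 5.60 ± 3.81 against 0.375 ± 0.285 CPM (log2 3.90 ± 0.67, adjusted p = 0.44). Other fits passed the threshold: DESeq2 at 3.94 (adjusted p = 0.000137), limma voom at 4.80 (adjusted p = 0.0409) and a fit over all eWAT libraries at 3.87 (adjusted p = 0.0367). Elovl3 was at 14.3 against 1.76 CPM (adjusted p = 0.44), Pck1, the enzyme of glyceroneogenesis, at 599 ± 282 against 198 ± 118 CPM (adjusted p = 0.93) and Hadha at 429 against 290 CPM (adjusted p = 0.85). Of the lists, oxidative phosphorylation had a median of log2 0.49 (31 of 52 higher adjusted over the list alone, adjusted p = 2.35e-36, adjusted p = 0.362 with an estimated correlation) and thermogenic genes of 0.66 (8 higher and 1 lower of 28 adjusted over the list alone, adjusted p = 1.13e-12, adjusted p = 0.259 with an estimated correlation). Fatty acid oxidation stood at 0.66 (adjusted p = 3.01e-18, adjusted p = 0.361 with an estimated correlation), the tricarboxylic acid cycle at 0.56 (adjusted p = 2.28e-15, adjusted p = 0.413 with an estimated correlation) and PPAR gamma targets at 0.53 (adjusted p = 5.64e-10, adjusted p = 0.482 with an estimated correlation). Rosi replicate 4 had 44.6% of reads in no gene feature (others 30.5 to 35.4%) and 1.89% of gene counts in Rn45s (others 0.677 to 1.30%). Each of these 5 medians was lowest without it, at 0.34, 0.31, 0.46, 0.35 and 0.25 in the order given, and highest without control replicate 1, at 0.61, 1.03, 0.87, 0.74 and 0.98. Pck1 went from log2 1.71 to 1.25 and 2.19 in these fits. The adipocyte gene Adipoq, chosen after seeing the data, was at 1643 ± 1031 CPM with rosi against 1099 ± 1007 CPM in control. Pparg, chosen likewise, was at 95.2 ± 32.5 against 89.8 ± 44.7 CPM. How far the share of adipocytes in each sample entered these list medians was not tested.

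Macrophage, matrix and proliferation lists had negative medians in that contrast, of -0.25 (adjusted p = 0.00702, adjusted p = 0.739 with an estimated correlation), -0.38 (adjusted p = 2.38e-06, adjusted p = 0.455 with an estimated correlation) and -0.30 (adjusted p = 2.61e-06, adjusted p = 0.53 with an estimated correlation). The interferon list was called too (camera adjusted p = 3.96e-05), though not with an estimated correlation. Its members named by the rule, Irf7, Iigp1, Oas2 and Oasl2, were at log2 0.80, 0.71, 0.59 and 0.55, none past the test. The direction of its other members is not given here. The spread between replicates was larger than in iWAT: the biological coefficient of variation was 0.265 here and 0.155 in B6 iWAT. The count was 1 gene without control replicate 1 and 88 in a fit over all eWAT libraries. Macrophage markers missed the threshold without control replicate 2 (adjusted p = 0.104) or 3 (0.31), and without rosi replicate 4 their direction turned (0.644).

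Whether rosi acted differently by strain in iWAT was tested as an interaction over the 16 libraries, where 12 genes were higher and 2 lower in 129. Serpina3n, lower with rosi in B6, was at 421 with rosi against 619 CPM in 129 control, an interaction of log2 2.28 ± 0.26 (adjusted p = 0.0021). Ephx2, an epoxide hydrolase, and Acacb responded less in 129, at -1.61 ± 0.27 and -1.07 ± 0.19 (adjusted p = 0.045 each). Lamb3, Serpina3m, Hp and Trabd2b had interactions of 1.40 ± 0.22, 2.36 ± 0.39, 2.17 ± 0.38 and 1.40 ± 0.24 (adjusted p = 0.045 each). Of these 7, the interaction of Serpina3n alone passed without any 1 library. The Ucp1 interaction was -4.18 ± 1.36 (adjusted p = 0.33), and -2.70 without 129 control replicate 3. Oxidative phosphorylation had a median interaction of -0.51 (27 of 52 lower adjusted over the list alone, adjusted p = 3.09e-31, adjusted p = 0.356 with an estimated correlation). The median was -0.63 for fatty acid oxidation (20 of 23 lower adjusted over the list alone, adjusted p = 9.7e-23, adjusted p = 0.259 with an estimated correlation) and -0.83 for thermogenic genes (5 of 29 lower adjusted over the list alone, adjusted p = 1.34e-07, adjusted p = 0.421 with an estimated correlation). Without 129 control replicate 3 the thermogenic median was -0.41. Endothelial markers had a median of 0.48 (6 of 15 higher adjusted over the list alone, adjusted p = 5.84e-10, adjusted p = 0.259 with an estimated correlation). The count of 14 rose to 54 without B6 rosi replicate 1 and 43 without 129 rosi replicate 1, and ran down to 1 in other such fits. DESeq2 called 96, limma voom with quality weights 65, and a fit over all iWAT libraries 7.

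The interaction of rosi with depot in B6 (eWAT against iWAT, 16 libraries, 2 runs) gave 0 genes by edgeR, with 590 at an unadjusted p under 0.05, 3 by DESeq2, 4 by limma voom with quality weights and 2 in a fit over all libraries of both depots. Ucp1 was at -0.73 ± 1.40 (adjusted p = 1.0) and Hadha at -0.73 ± 0.20 (adjusted p = 0.96). Oxidative phosphorylation had a median of -0.30 (adjusted p = 4.08e-13, adjusted p = 0.523 with an estimated correlation), interferon genes of 0.41 (adjusted p = 2.15e-06, adjusted p = 0.424 with an estimated correlation) and endothelial markers of 0.40 (adjusted p = 1.03e-05, adjusted p = 0.458 with an estimated correlation). Thermogenic genes had a median of -0.11 and no call (adjusted p = 0.508). Whether eWAT and iWAT libraries of equal number came from the same animals was not checked, and the main fit took them as independent.

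**Figure D2:**
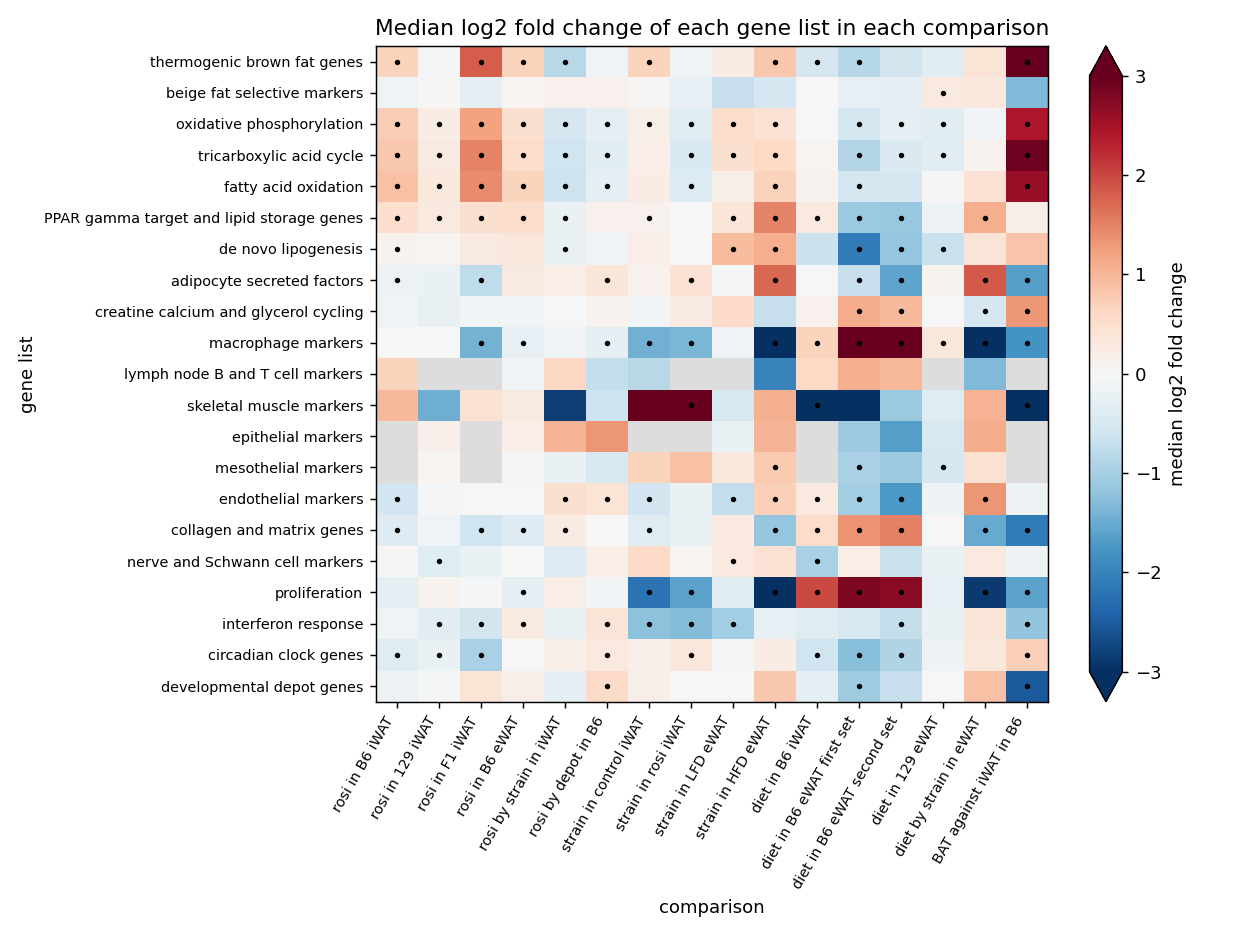
Median log2 fold change of 21 gene lists (y axis) in 16 comparisons (x axis), on a colour scale that ends at -3 and 3, with a black dot where camera passed with the preset correlation and light grey where fewer than 3 genes were tested. Oxidative phosphorylation stood at 0.75 with rosi in B6 iWAT, 1.21 in F1 iWAT, 0.23 in 129 iWAT and 0.49 in B6 eWAT.

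The strains were compared next, 129 against B6, to describe the background in which Ucp1 differs. In iWAT of HFD control mice (4 against 4), Ucp1 was higher in 129 (58.5 ± 74.9 against 0.780 ± 0.566 CPM, log2 6.24 ± 1.03, adjusted p = 0.0014), at 4.76 without 129 replicate 3. Cidea, a lipid droplet protein of brown fat, was at 80.2 ± 42.8 against 14.9 ± 5.66 CPM (log2 2.41 ± 0.36, adjusted p = 0.00081). In all, 1508 genes were higher and 2081 lower of 12894. Reads in no gene feature made up 33.1 to 35.5% in 129 and 36.0 to 39.6% in B6. Nnt, whose mitochondrial enzyme C57BL/6J lacks, was higher in 129 at 25.6 ± 2.70 against 15.4 ± 1.23 CPM (log2 0.71 ± 0.11). Hal, which degrades histidine, was at log2 8.02 ± 0.15. Rprl3 was at 273 CPM in 129 and had no counts in B6, at least 2547-fold higher over a floor of 3 counts in the group. Trim12a had no counts in 129 and 18.6 CPM in B6, at least 163-fold lower. Grid1, Tfr2, Unc5a and Pttg1 were lower in 129, from -7.86 ± 0.43 to -4.99 ± 0.23.

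Scd1, which desaturates fatty acids, was at 69938 ± 11190 CPM in 129 and 16741 ± 2660 CPM in B6 iWAT control (log2 2.04 ± 0.15, adjusted p = 6.7e-06). Cfd (log2 1.89 ± 0.32) and Pck1 (1.86 ± 0.20) were also higher in 129, and the malic enzyme Me1 was lower (-1.66 ± 0.13). Proliferation genes were lower: 15 of 17, in both counts, with Mcm6 at 4.05 against 24.5 CPM (median -2.23, adjusted p = 1.09e-14, adjusted p = 0.331 with an estimated correlation). Macrophage markers had 18 of 23 lower and 0 higher (19 adjusted over the list alone), the galectin Lgals3 at 48.4 against 191 CPM (adjusted p = 1.22e-06, adjusted p = 0.53 with an estimated correlation). Interferon genes had 16 of 18 lower (17 adjusted over the list alone), the antiviral Rsad2 at 4.26 against 31.5 CPM (adjusted p = 1.09e-08, adjusted p = 0.429 with an estimated correlation). Endothelial markers had 12 of 15 lower, Tie1 at -1.04 ± 0.12 (adjusted p = 2.18e-05, adjusted p = 0.413 with an estimated correlation). Thermogenic genes had 12 of 27 higher and 3 lower (13 and 3 adjusted over the list alone), with a median of 0.66 (adjusted p = 0.00444, adjusted p = 0.681 with an estimated correlation). Muscle markers had 12 of 15 higher and a median of 6.37 without a call (adjusted p = 0.103), Myh4 being at 2762 ± 5449 against 16.1 ± 17.5 CPM, and its call held in 4 of 8 leave-one-out fits. The muscle list passed without 129 replicate 1 (adjusted p = 0.0082) or 4 (0.00951). Strain and lane could not be told apart in iWAT.

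With rosi, 918 genes were higher and 1090 lower in 129 iWAT of 12537 tested (4 against 4), counts that summed to 1198 without B6 replicate 4, 1329 without 129 replicate 4 and 1037 with a muscle covariate chosen after seeing the data. Ucp1 was higher in 129 (80.1 ± 37.2 against 18.8 ± 12.8 CPM, log2 2.07 ± 0.57, adjusted p = 0.034), and the call was lost without B6 replicate 3 or 4 or 129 replicate 1, 2 or 3 (log2 1.71 to 2.36, highest adjusted p = 0.0834) and in a fit over all iWAT libraries (adjusted p = 0.208). Sptlc3 and Elovl3, which rosi had raised in B6, were lower in 129, at 1.12 against 53.0 CPM (log2 -5.62 ± 0.43, adjusted p = 2.5e-05) and 3.76 against 61.0 CPM (log2 -4.00 ± 0.43, adjusted p = 0.00019). Fatty acid oxidation had 7 of 23 lower and 0 higher (10 adjusted over the list alone), Acadl at -1.59 ± 0.20 (adjusted p = 9.61e-05, adjusted p = 0.595 with an estimated correlation). Oxidative phosphorylation had 11 of 52 lower and 0 higher (adjusted p = 1.19e-05, adjusted p = 0.703 with an estimated correlation). Macrophage markers (12 of 23 lower, 16 adjusted over the list alone) and interferon genes (15 of 18 lower, 16 adjusted over the list alone) were lower again, Rsad2 at -2.62 ± 0.20 (adjusted p = 1.22e-06 and 6.71e-14, adjusted p = 0.59 and 0.303 with an estimated correlation). Cfd was at 2054 against 272 CPM. Muscle markers had a median of 3.23 (3 of 16 higher, adjusted p = 0.00488, adjusted p = 0.703 with an estimated correlation, and adjusted p = 0.0506 without 129 replicate 1), and Mb, the oxygen carrier of muscle, was higher in 129 by 6.89 ± 1.06. Nnt was higher by 0.93 ± 0.26 (adjusted p = 0.036), a call that held in 2 of 8 leave-one-out fits.

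In eWAT of LFD mice (4 against 4, 1 lane), 2016 genes were higher and 2034 lower in 129 of 12523. Signs of RNA quality differed with strain: reads in no gene feature made up 32.3 to 36.7% in 129 and 39.3 to 49.1% in B6, and Rn45s took 0.318 to 0.658% and 0.748 to 1.65% of gene counts. Oxidative phosphorylation was higher, 48 of 52 genes with 0 lower (49 adjusted over the list alone), Ndufb5 at log2 0.68 ± 0.09 (adjusted p = 1.27e-15, adjusted p = 0.446 with an estimated correlation). De novo lipogenesis had 9 of 16 higher and 0 lower, in both counts, Scd2 at 1.67 ± 0.26 (adjusted p = 0.000427, adjusted p = 0.53 with an estimated correlation). Endothelial markers had 12 of 15 lower (13 adjusted over the list alone), Cdh5 at -1.19 ± 0.15 (adjusted p = 3.07e-07, adjusted p = 0.455 with an estimated correlation). Interferon genes had 13 of 17 lower and 1 higher (14 and 1 adjusted over the list alone), Rsad2 at -2.37 ± 0.25 (adjusted p = 3.4e-05, adjusted p = 0.456 with an estimated correlation). Cidea was at 25.5 ± 2.95 against 3.56 ± 1.07 CPM (log2 2.76 ± 0.20), Nnt at 54.5 ± 5.43 against 26.1 ± 2.88 CPM (log2 1.01 ± 0.12) and the cystine carrier Slc7a11 at 5.04 ± 0.16 (adjusted p = 4.5e-09). Trem2, a receptor of lipid-handling macrophages, was at 94.8 against 12.4 CPM, while the macrophage list was not called (median -0.10, test upwards, adjusted p = 0.821). Nlrp1c-ps had no counts in 129 and 10.1 CPM in B6. Ucp1 was under the count filter (4.48 ± 5.64 against 0.732 ± 0.305 CPM). The liver gene Apob was at 2.30 against 101 ± 184 CPM (log2 -5.45 ± 1.42, adjusted p = 0.012), and at -1.96 without B6 replicate 3.

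In eWAT of HFD mice (4 against 4, 1 lane), 3347 genes were higher and 3812 lower in 129 of 13206, and Ucp1 was at 5.56 ± 2.32 against 0.375 ± 0.285 CPM (log2 3.85 ± 0.51, adjusted p = 0.00035). Macrophage markers were lower: 24 of 25 with 0 higher, in both counts, Adgre1 at 91.1 ± 9.97 against 822 ± 280 CPM and Atp6v0d2 at 12.4 against 507 CPM (median -3.31, adjusted p = 3.53e-16, adjusted p = 0.413 with an estimated correlation). Proliferation genes had 17 of 18 lower, Bub1b at -3.93 ± 0.17 (adjusted p = 1.32e-27, adjusted p = 0.259 with an estimated correlation), and matrix genes 15 of 22 lower and 2 higher (15 and 3 adjusted over the list alone), the protease inhibitor Timp1 at -3.34 ± 0.25 (adjusted p = 0.000778, adjusted p = 0.468 with an estimated correlation). PPAR gamma targets had 20 of 31 higher and 5 lower (21 and 5 adjusted over the list alone), Pck1 at 3719 ± 665 against 198 ± 118 CPM (adjusted p = 0.00164, adjusted p = 0.703 with an estimated correlation). Secreted factors had 12 of 17 higher (13 adjusted over the list alone), Nnat at 4.54 ± 0.66 (adjusted p = 0.000737, adjusted p = 0.638 with an estimated correlation). Scd1 was at 86847 against 6929 CPM, the beta-3 adrenergic receptor Adrb3 at 409 against 33.7 CPM (log2 3.63 ± 0.43) and Dio2, which activates thyroid hormone, was lower by log2 -3.12 ± 0.30. Nnt was at 44.3 ± 6.53 against 25.4 ± 3.72 CPM.

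Diet was compared as HFD against LFD, first in B6 iWAT (4 against 4, 1 lane). There 1547 genes were higher and 1465 lower on HFD of 13240. Muscle markers took 0.605 to 6.01% of counts on LFD and 0.0103 to 0.0257% on HFD. How far muscle RNA entered the other changes given here, among them those of Ppargc1a and the thermogenic list, was not tested. Proliferation genes rose on HFD, 16 of 17 in both counts, Mki67 from 9.62 to 46.9 CPM (median 1.98, adjusted p = 2.66e-24, adjusted p = 0.259 with an estimated correlation). Leptin (Lep) rose from 2211 to 5636 CPM (log2 1.35 ± 0.27), and Pck1, Scd1 and Cfd fell by log2 values of -1.74 ± 0.25, -1.56 ± 0.30 and -2.42 ± 0.35. Ppargc1a, a coactivator of mitochondrial genes, fell by 1.76 ± 0.28. Thermogenic genes had 11 of 28 lower and 3 higher (11 and 5 adjusted over the list alone, adjusted p = 0.0245, adjusted p = 0.703 with an estimated correlation), a call lost without HFD replicate 2 (0.0927) or LFD replicate 3 (0.569). Clock genes had 9 of 14 lower and 1 higher (10 and 1 adjusted over the list alone), Hlf at -1.19 ± 0.11 (adjusted p = 7.06e-05, adjusted p = 0.429 with an estimated correlation). Matrix genes had 8 of 22 higher and 1 lower, Postn at 1.42 ± 0.21 (adjusted p = 0.0013, adjusted p = 0.595 with an estimated correlation). Nerve markers had 5 of 10 lower and 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.00583, adjusted p = 0.53 with an estimated correlation). Macrophage markers had 4 of 24 higher (0 adjusted over the list alone, adjusted p = 0.0281, adjusted p = 0.752 with an estimated correlation), among them Lgals3 (71.7 to 191 CPM, adjusted p = 0.02), which passed in 5 of 8 leave-one-out fits. The list missed without HFD replicate 3 (0.178) or 4 (0.085) or LFD replicate 1 (0.064) or 3 (0.148).

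All 18 skeletal muscle markers were lower on HFD in B6 iWAT (18 adjusted over the list alone), Myh4 at 16.1 against 10757 CPM (median -7.54, adjusted p = 1.38e-29, adjusted p = 0.259 with an estimated correlation). Ano5 had no counts on HFD and 52.2 CPM on LFD, at least 487-fold lower. Muscle markers took 0.605 to 6.01% of the counts of the LFD libraries and 0.0103 to 0.0257% of those on HFD. Without the 364 genes that followed muscle markers across 129 iWAT (a set chosen after seeing the data), 2739 genes were called. Ucp1 was under the count filter, at 0.780 ± 0.566 against 38.8 ± 76.7 CPM, with 154 CPM in LFD replicate 3.

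**Figure D3:**
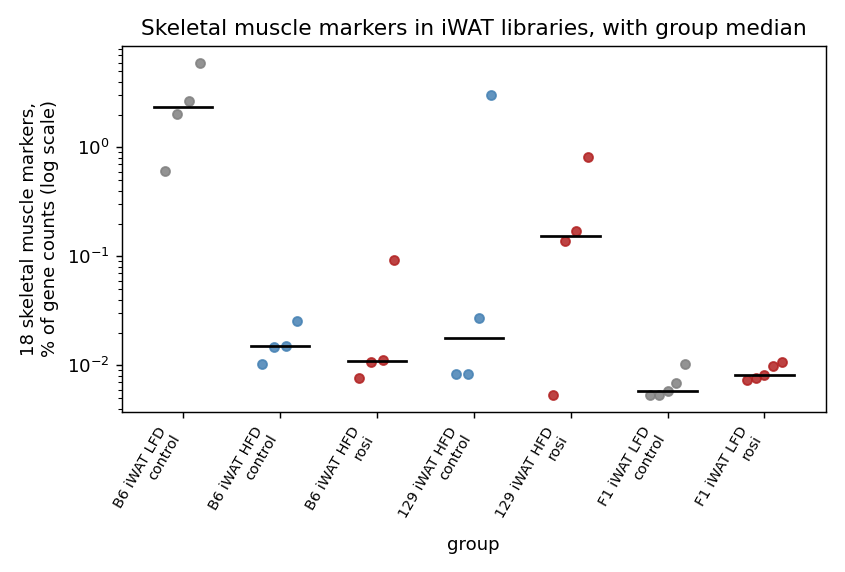
Summed share of 18 skeletal muscle markers among gene counts (%, log scale) in each library of the 7 iWAT groups on the x axis, with a bar at the group median. The 4 libraries of B6 LFD control lay between 0.605 and 6.01%, 129 HFD control replicate 3 was at 3.06% and 129 HFD rosi replicate 1 at 0.814%.

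In the first set of B6 eWAT (5 against 5, 1 lane), 3672 genes were higher and 3553 lower on HFD of 12447. Macrophage markers rose, 24 of 25 with 1 lower in both counts (median 3.93, adjusted p = 8.19e-28, adjusted p = 0.259 with an estimated correlation). Trem2 rose from 5.89 ± 1.57 to 371 ± 150 CPM (log2 5.96 ± 0.33, adjusted p = 5.3e-08) and Lgals3 from 115 to 2229 CPM. Gpnmb, Spp1 (osteopontin) and the elastase Mmp12, known from lipid-laden macrophages, rose by 7.53 ± 0.44, 8.03 ± 0.74 and 7.91 ± 0.59. De novo lipogenesis fell, 14 of 16 with 0 higher, Acaca from 2816 ± 829 to 267 ± 129 CPM (median -2.10, adjusted p = 9.56e-07, adjusted p = 0.468 with an estimated correlation). Tricarboxylic acid cycle genes had 17 of 18 lower (adjusted p = 7.95e-07, adjusted p = 0.52 with an estimated correlation). Oxidative phosphorylation had 46 of 52 lower and 1 higher (47 and 1 adjusted over the list alone, adjusted p = 2.83e-09, adjusted p = 0.53 with an estimated correlation), and PPAR gamma targets 24 of 31 lower and 6 higher (adjusted p = 0.000434, adjusted p = 0.595 with an estimated correlation). Adrb3 fell from 504 to 64.8 CPM and Cfd from 6987 to 299 CPM, and the lipid droplet coat Plin2 rose by 2.20 ± 0.21. Chosen after seeing the data, Adipoq was at 1154 ± 454 CPM on HFD against 4002 ± 150 CPM on LFD. Pparg was at 138 ± 59.2 against 317 ± 18.8 CPM, while Lep was at 2135 ± 1240 against 1631 ± 367 CPM. RNA came from whole tissue, so here and in the other comparisons the share of cell types and expression per cell could not be told apart.

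Matrix and proliferation genes rose in the same set, 18 of 22 (Timp1 at 4.67 ± 0.20) and 16 of 17 (Top2a at 3.36 ± 0.18), with adjusted p = 4.55e-10 and 2.04e-18 (adjusted p = 0.33 and 0.259 with an estimated correlation). All 15 endothelial markers fell, Kdr at -1.38 ± 0.21 (adjusted p = 0.000161, adjusted p = 0.59 with an estimated correlation). All 9 mesothelial markers fell (adjusted p = 0.00345, adjusted p = 0.59 with an estimated correlation), as did 10 of 14 clock genes with 2 higher, Per3 at -2.01 ± 0.10 (adjusted p = 2.88e-05, adjusted p = 0.361 with an estimated correlation). Creatine and glycerol cycling genes had 6 of 8 higher (6 and 2 lower adjusted over the list alone), the brain-type creatine kinase Ckb at 2.68 ± 0.25 (adjusted p = 0.0206, adjusted p = 0.33 with an estimated correlation). Ucp1 was under the count filter, with no counts in any of 5 LFD libraries and 0.517 ± 0.944 CPM on HFD.

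The second set of B6 eWAT (4 against 4, diet and run together) had 3371 genes higher and 3182 lower of 13106. Reads in no gene feature made up 33.9 to 36.4% on HFD and 39.3 to 49.1% on LFD, with no overlap. It shared 2785 higher and 2396 lower genes with the first set, where independence would give 962 and 841, and 5 and 8 genes went opposite ways (a comparison chosen after seeing the data). Adgre1 rose from 71.9 to 822 CPM, with 23 of 24 macrophage markers higher and 1 lower in both counts (adjusted p = 1.31e-15, adjusted p = 0.413 with an estimated correlation). Pck1 fell from 3603 to 198 CPM. The endothelial list had 15 of 15 lower, Kdr at -2.10 ± 0.31 (adjusted p = 6.95e-08, adjusted p = 0.458 with an estimated correlation). Secreted factors had 10 lower and 0 higher, Agt, the source of angiotensin, at -3.48 (adjusted p = 0.00044, adjusted p = 0.59 with an estimated correlation). The liver genes Alb, Apob, Serpina3k, Tat and Itih4 were lower on HFD, Alb at 1.26 against 276 ± 522 CPM (log2 -7.81 ± 1.88), and Alb was at -3.65 without LFD replicate 3, which held 1059 CPM.

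**Figure D4:**
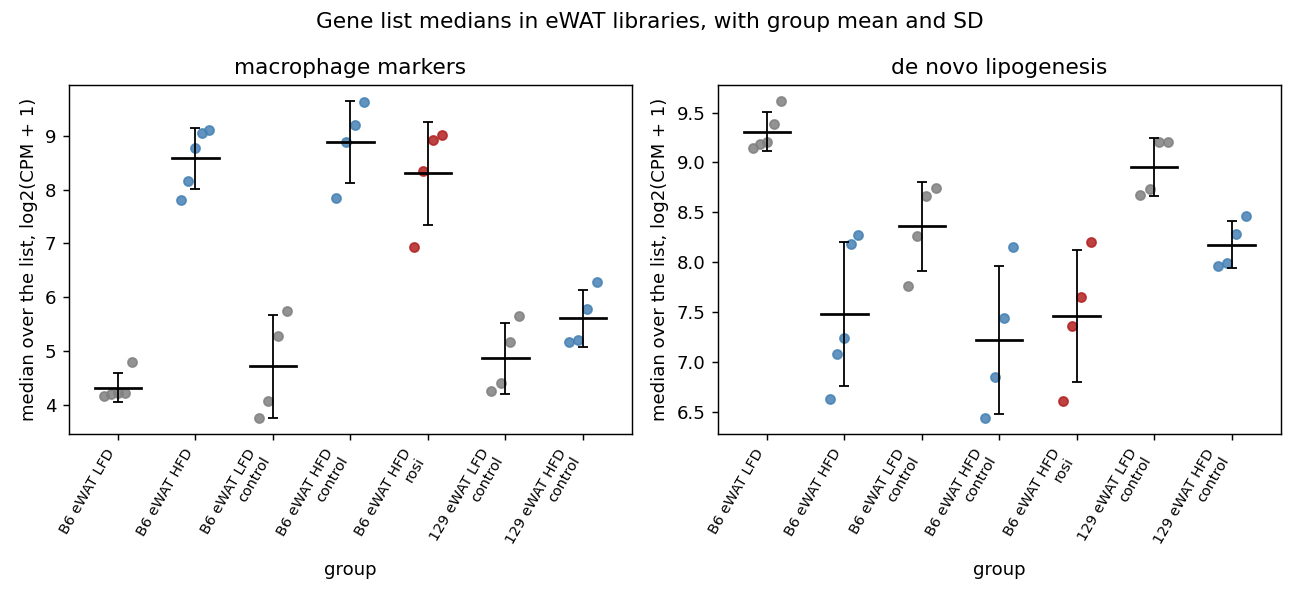
Median log2(CPM + 1) of macrophage markers (left) and de novo lipogenesis genes (right) in each library of the 7 eWAT groups on the x axes, with the group mean and an error bar of 1 SD. The fitted median change on HFD in macrophage markers was log2 3.93 in the first set of B6 and 0.35 in 129.

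In 129 eWAT (4 against 4, diet and run together), 1493 genes were higher and 1164 lower on HFD of 12554. De novo lipogenesis fell here too, 11 of 16 with 0 higher in both counts, Fasn, fatty acid synthase, from 15409 ± 5786 to 3656 ± 1081 CPM (median -0.66, adjusted p = 3.99e-12, adjusted p = 0.303 with an estimated correlation). Oxidative phosphorylation had 30 of 52 lower (38 adjusted over the list alone, adjusted p = 5.31e-17, adjusted p = 0.413 with an estimated correlation) and the tricarboxylic acid cycle 12 of 18 lower (adjusted p = 3.71e-06, adjusted p = 0.53 with an estimated correlation). Macrophage markers had 7 of 22 higher and 1 lower (8 and 1 adjusted over the list alone), Clec7a from 7.95 to 16.0 CPM (median 0.35, adjusted p = 0.0223, adjusted p = 0.743 with an estimated correlation). This list missed without LFD replicate 3 (0.176) or 4 (0.0737) or HFD replicate 2 (0.144). Pdk4 rose from 65.2 to 221 CPM, and the imprinted genes Peg3 and Mest rose by 2.36 ± 0.19 and 1.42 ± 0.17. Matrix genes had a median of -0.02 and a mean of 0.13 (adjusted p = 0.174, and 0.0388 without HFD replicate 3). A fit over all eWAT libraries called 919 genes. Ucp1 was at 5.56 ± 2.32 against 4.48 ± 5.64 CPM (log2 0.24 ± 0.59, adjusted p = 0.81), and at 1.60 (adjusted p = 0.0329) without LFD replicate 3.

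Whether diet acted differently by strain in eWAT was tested as an interaction (16 libraries), where 2531 genes were higher and 2908 lower in 129 of 13523. Reads in no gene feature made up 39.3 to 49.1% in the B6 LFD group and 30.3 to 36.7% in the other 3, and B6 LFD replicate 3 held Alb at 1059 CPM. Macrophage markers rose less in 129, 23 of 24 with a negative interaction in both counts (median -3.24, adjusted p = 2.59e-15, adjusted p = 0.361 with an estimated correlation). Trem2 was at 78.4 on HFD against 94.8 CPM on LFD in 129, an interaction of log2 -5.05 ± 0.56. Proliferation (17 of 18, median -2.87, Mcm5 at -2.85 ± 0.29, adjusted p = 4.13e-14, adjusted p = 0.259 with an estimated correlation) had a negative sign too. So did matrix genes (16 of 22 lower and 1 higher, 17 and 1 adjusted over the list alone, Col3a1 at -2.87, adjusted p = 1.58e-06, adjusted p = 0.364 with an estimated correlation). Endothelial markers had 14 of 15 positive, in both counts, Robo4 at 2.09 ± 0.35 (adjusted p = 8.83e-07, adjusted p = 0.454 with an estimated correlation). Pck1 was at 3719 against 3464 CPM in 129, an interaction of 4.37 ± 0.47, and PPAR gamma targets had 14 positive and 3 negative (19 and 3 adjusted over the list alone, adjusted p = 0.00688, adjusted p = 0.703 with an estimated correlation). Ucp1 had an interaction of 1.24 ± 1.32 (adjusted p = 0.48), and of 2.61 (adjusted p = 0.0448) without 129 LFD replicate 3. The nerve list's median of 0.29 and mean of 0.16 differed in sign from its test (adjusted p = 0.885).

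BAT of B6 mice on HFD, with no agent named in the labels, was compared with iWAT of HFD control mice (4 against 4), which gives the distance between the depots. Ucp1 was higher in BAT by 12.87 ± 0.32 on the log2 scale (adjusted p = 1.2e-09), with 3987 genes higher and 4130 lower of 12439. Of 34 thermogenic genes, 33 were higher, Fabp3 at 1416 against 0.749 CPM and Cox7a1 at log2 6.93 ± 0.15. Their median was 4.52, also with Zic1, which had no counts in iWAT, at its bound (adjusted p = 2.55e-53, adjusted p = 0.259 with an estimated correlation). Oxidative phosphorylation had 50 of 52 higher and 2 lower, Cyc1 at 3.50 ± 0.13 (adjusted p = 5.6e-62, adjusted p = 0.259 with an estimated correlation), and fatty acid oxidation 22 of 23 higher and 1 lower, Acadvl at 4.21 ± 0.14 (adjusted p = 6.98e-36, adjusted p = 0.259 with an estimated correlation). Beige markers had 1 of 7 higher and 5 lower, with no call (median -1.33, adjusted p = 0.0509). They passed with the replicate number as a block, which pairs these libraries (adjusted p = 0.0445), and without iWAT replicate 3 or 4 or BAT replicate 2 or 4 (0.0204 to 0.05). Of 13 depot genes, 9 were lower and 2 higher, with a median of -2.53, also with the 3 genes that had no counts in BAT at their bounds (adjusted p = 0.00793, adjusted p = 0.429 with an estimated correlation). Hoxc8 was at log2 -3.59 ± 0.29 and Hoxa5 at 2.73 ± 0.19, and Hoxa10 had no counts in BAT and 14.0 CPM in iWAT, at least 69.1-fold lower. Matrix genes had 20 of 22 lower and 1 higher (adjusted p = 1.43e-06, adjusted p = 0.53 with an estimated correlation) and macrophage markers 18 of 24 lower (19 adjusted over the list alone), Cd163 at -2.84 ± 0.23 (adjusted p = 0.0113, adjusted p = 0.743 with an estimated correlation). Secreted factors had 12 lower and 3 higher, resistin (Retn) at 20.9 against 529 CPM (adjusted p = 0.0245, adjusted p = 0.413 with an estimated correlation). Clock genes had 10 higher and 0 lower, Hlf at 2.61 ± 0.14 (adjusted p = 0.0184, adjusted p = 0.458 with an estimated correlation). Rn45s took 0.304 to 0.442% of gene counts in BAT and 0.492 to 0.807% in iWAT. Depot and run could not be told apart.

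Across genes, which are not independent replicates, the log2 fold changes of diet in the first set and of rosi in the second set, which share no libraries, correlated at Pearson -0.42 and Spearman -0.50. Of 7100 genes called for diet, 75.5% had the opposite sign with rosi, where no gene was called, and the share that other groupings of these libraries would give was not computed. The diet effect of the first set correlated with that of the second at Pearson 0.92 and with that in 129 at 0.30, both chosen after seeing the data.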

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

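The tests of the low-fat diet, the sequencing lane and the depth of 129 libraries were chosen after the values they rest on were seen, and the other tests before. Libraries were compared within groups of 4 or 5 for totals, genes detected, the share of reads in no gene feature, muscle markers, Ucp1 and Alb. Of 89 comparisons, 14 held a library far from the others. For normally distributed values chance would give about 1 in 20 groups, or 4.45, and CPM and percentages need not be so distributed.

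The first pattern was skeletal muscle RNA in all 4 B6 iWAT LFD control libraries, at 0.605 to 6.01% of counts, beside 3.06% in 129 HFD control replicate 3, whose group was otherwise at 0.00827 to 0.0269%. The low-fat diet as the only cause was argued against, since the highest of the F1 LFD libraries, of another strain and run, held 0.0106% and a 129 HFD library held 3.06%, and so was the lane, since the HFD control libraries of the same lane held at most 0.0257%. Muscle tissue taken with the fat stayed open: over 18 markers, the log2 ratio of the B6 LFD mean to that 129 library had an SD of 1.67, between the bounds of 1 and 2 set for yes and no. A difference in muscle-like gene expression between diets in B6 was not tested.

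The second pattern was Ucp1 at 171 CPM in 129 iWAT HFD control replicate 3 (others 17.8 to 26.5) and 154 CPM in B6 iWAT LFD control replicate 3 (others 0.236 to 0.794). Brown fat in these libraries is a candidate source: 30 BAT-selective genes other than Ucp1 gained a median of 2.24% and 2.92% of their BAT level, where Ucp1 gained 2.67% and 2.7%, and 28 of 30 gained in each. Cidea was at 142 CPM in both, against 2019 in BAT, and Zic1, at 4.21 CPM in BAT, was at 0 and 0.231 CPM, too near the floor to decide. Beige cells could express many of the same genes, which was not tested. For a mislabelled rosi library, the shift along 1201 rosi-responsive genes decided nothing. It was 0.0829 where rosi libraries moved by 0.244, and 0.142 against 0.48. The Ucp1 level itself argues against a rosi library of the same strain, more clearly in B6. The 171 CPM lay above 129 iWAT HFD rosi (80.1 ± 37.2 CPM), and the 154 CPM above B6 iWAT HFD rosi (18.8 ± 12.8 CPM).

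The third pattern was the 14 genes called for rosi in 129 iWAT against 1689 in B6. A muscle covariate gave 21 genes, under the bound set against muscle RNA as a cause. The covariate was a single term, linear in the log marker level, and need not remove all spread from muscle RNA. This cause is therefore not excluded. Lower depth was argued against by a ratio of totals of 1.03. The spread between replicates was larger in 129, with a coefficient of variation of 0.211 against 0.155 in B6. Simulated 1.5-fold changes were recovered in 22.4% against 37.3% of genes, and 2-fold changes in 77.6% against 74.6%. How far this spread lowered the count was not tested. A smaller response in 129 may contribute: along the 1201 F1 genes the median change was 0.217 in 129 and 0.48 in B6, a ratio of 0.453, but this ran from 0.373 without 129 rosi replicate 1 to 0.603 without 129 rosi replicate 4 and stayed open. As another measure, the mean over these genes in the F1 direction was taken per library and compared between rosi and control. The exact permutation p of that mean was 0.0571 in 129 and 0.0286 in B6, the latter the smallest that 4 against 4 can give.

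Other libraries stood apart in single values. Total counts were 9551251 in B6 iWAT HFD rosi replicate 4 (others 5353293 to 5435723) and 4926807 in B6 iWAT LFD control replicate 2 (others 8352763 to 8844543). Genes detected were 21330 in B6 eWAT HFD rosi replicate 4 (others 16781 to 17085) and 16878 in F1 iWAT LFD control replicate 1 (others 15471 to 15861). Muscle markers took 0.336% in B6 eWAT LFD replicate 3 of the first set (others 0.00795 to 0.0186%), 0.0928% in B6 iWAT HFD rosi replicate 4 (others 0.00773 to 0.0111%) and 0.00927% in 129 eWAT LFD control replicate 2. Ucp1 was at 2.20 CPM in B6 eWAT HFD replicate 3 of the first set (others 0 to 0.225). The liver gene Alb was at 1059 CPM in B6 eWAT LFD control replicate 3 (others 11.7 to 18.4), 49.98 CPM in B6 iWAT HFD rosi replicate 1 (others 3.18 to 9.26) and 449 CPM in F1 iWAT LFD control replicate 1 (others 46.0 to 72.5).

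Differences between groups passed an interaction test for 14 genes for rosi by strain in iWAT, and 5439 for diet by strain in eWAT.

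Other splits of the same libraries into groups of the same sizes were fitted to ask how often chance gives as many genes. A share of 1 of 35, or 2.86%, is the smallest that 35 splits can give, and shares were not adjusted over the comparisons. Low shares therefore argue against chance without excluding it. For rosi in B6 iWAT, 1 of 35 splits, the real one, gave as many (1689, highest other 142). In 129 iWAT 1 of 35 did too (14 against 5), though there the count fell to 0 in 5 of 8 fits that left out 1 library. In F1 iWAT 1 of 100 drawn of 126 did (4483 against 5). The same held for strain in control iWAT (1 of 35, 3589 against 0), rosi iWAT (1 of 35, 2008 against 1), LFD eWAT (1 of 35, 4050 against 0) and HFD eWAT (1 of 35, 7159 against 0). It held for diet in B6 iWAT (1 of 35, 3012 against 3), the first set of B6 eWAT (1 of 100 drawn of 126, 7225 against 0), the second set (1 of 35, 6553 against 0), 129 eWAT (1 of 35, 2657 against 1) and BAT against iWAT (1 of 35, 8117 against 0). For rosi in B6 eWAT, 35 of 35 splits gave at least the real 0 (highest other 0), as any split must, so this decides nothing. Among interactions, 100 of 2450 splits were drawn for each. For rosi by strain, 8 gave as many as the real 14 (highest other 1579), for rosi by depot all 100 did (real 0, highest other 1859), as any split must, and for diet by strain 2 did (real 5439, highest other 5579). Such splits also break the effect within each strain or depot, so they decide nothing on chance for an interaction. All 5 other splits that called any gene for diet by strain kept the B6 groups whole and mixed those of 129, as did 5 of the 7 that reached 14 genes for rosi by strain. The highest for rosi by depot kept the iWAT groups whole. Such splits carry the effect of the groups kept whole by construction. The 2 others for rosi by strain, at 115 and 59 genes, and 1 for rosi by depot, at 526, point to a structure of the samples that was not traced.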

How the results depend on the processing

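The muscle covariate, and the set without genes that follow muscle, were chosen after seeing the data, and all other alternatives before. Of 22011 alternative values of 1403 named gene results, 0 turned a called direction, 730 lost a call, 257 gained one, 114 turned the sign of a value that was not called, and 20910 kept both direction and side of the threshold. The direction of a called list turned in 2 fits, both for macrophage markers: for rosi in B6 eWAT without B6 eWAT rosi replicate 4 (adjusted p = 0.644), and for rosi by depot without B6 iWAT rosi replicate 1 (0.823). For the count of each comparison and its Ucp1 value, the changes were these, and the cause was not tested unless a reason is given. RLE scaling and no filter on low counts moved no count by over 1.5 times and changed no Ucp1 call. RLE moved the median of all genes by at most 0.0320 and the share of higher genes in B6 iWAT with rosi from 51.7% to 59.1%.

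DESeq2 called 193 genes for rosi in 129 iWAT, 32 in B6 eWAT, 96 for rosi by strain and 3 for rosi by depot. It placed Ucp1 in B6 eWAT with rosi at 3.94, past the threshold (adjusted p = 0.000137, 0.000137 to 1.0 over all alternatives). Limma voom with quality weights called 26, 32, 65 and 4 genes in the same order, with Ucp1 at 4.80 in B6 eWAT (adjusted p = 0.0409) and 0.25 for rosi by depot, where it was at -0.73 by edgeR and was not called by either. On simulated counts, DESeq2 made 46 false calls where edgeR made 4 for rosi in B6 eWAT, 21 against 3 in 129 iWAT, 26 against 7 for rosi by strain and 26 against 10 in B6 iWAT. A single fit over all libraries of a tissue called 29 genes for rosi in 129 iWAT, 88 in B6 eWAT, 7 for rosi by strain, 2 for rosi by depot and 919 for diet in 129 eWAT. With it Ucp1 was at 4.64 for rosi in B6 iWAT, no longer past the threshold (adjusted p = 0.0707, 9.0e-06 to 0.0707 over all alternatives). It was at 2.07 for strain in rosi iWAT, also not past it (adjusted p = 0.208, 0.0197 to 0.208), and at 3.87 for rosi in B6 eWAT, past it (adjusted p = 0.0367).

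The replicate number as a block gave 1028 genes for rosi in B6 iWAT, 4 in 129 iWAT, 2 for rosi by strain and 1259 for strain in rosi iWAT, with Ucp1 there at 2.12 (adjusted p = 0.098). The numbers did not pair libraries in these comparisons (r from -0.322 to 0.301 in B6 iWAT), and in BAT against iWAT, where they did, the block left the count of genes within 1.5 times and the Ucp1 call as it was. It changed the call of 15 list tests, among them beige markers for BAT against iWAT (adjusted p = 0.0445). The muscle covariate gave 1037 genes for strain in rosi iWAT.

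A limit of log2 1 removes small changes by construction. It left 311 genes for rosi in B6 iWAT, 1201 in F1, 1079 for strain in control iWAT, 806 in rosi iWAT, 739 in LFD eWAT and 3160 in HFD eWAT. For diet it left 831 in B6 iWAT, 2560 in the first and 3172 in the second set of B6 eWAT, 162 in 129 eWAT and 2935 for diet by strain, and 3689 for BAT against iWAT. Overlaps of rosi in B6 iWAT became 2 higher and 7 lower genes with 129, and 84 higher and 88 lower with F1. With an estimated correlation, 0 lists were called where 151 of 320 tests were before. Leaving out each library in turn gave 146 to 160 called lists in all, with both losses and gains among them.

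Leaving out each library in turn gave 929 (B6 rosi replicate 4) to 2542 genes (B6 rosi replicate 1) for rosi in B6 iWAT. It gave 0 to 40 (129 rosi replicate 4) for 129 iWAT, 0 in 5 of 8 fits, and 1 in B6 eWAT without control replicate 1. For rosi by strain it gave 1 to 54 (B6 rosi replicate 1), and for strain in rosi iWAT 1198 (B6 rosi replicate 4) to 1902. Ucp1 ran from 1.71 to 2.36 for strain in rosi iWAT, and lost its call in 5 of 8 fits. For diet in 129 eWAT it ran from -0.14 without LFD replicate 1 to 1.60 without LFD replicate 3, where it was called (adjusted p = 0.0329, 0.0329 to 0.987 over all alternatives). For diet by strain it ran from 0.87 to 2.61, called without the same library (adjusted p = 0.0448, 0.0448 to 0.649). Simulated changes of 1.5, 2 and 4-fold were recovered in 1.49%, 37.3% and 83.3% of genes for rosi in B6 eWAT and in 37.3%, 74.6% and 92.4% in B6 iWAT. Common dispersion as a coefficient of variation was 0.265 and 0.155 there, at similar depth, and the effect of depth alone was not tested.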

Other observations

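No test in this part was run beyond those named above, and the values below were looked at after the data were seen, with no explanation offered.

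Scd1 alone took 8.42% of gene counts in 129 eWAT on HFD and 0.709% in B6 eWAT on HFD. In F1 iWAT it took 8.97% in control and 7.89% in rosi libraries. The clock gene Dbp was lower with rosi in B6 iWAT (log2 -0.79 ± 0.14, adjusted p = 0.0051) and F1 iWAT (-1.72 ± 0.16), and at -0.89 ± 0.21 in 129 iWAT (adjusted p = 0.18). The labels give no time of day. Trabd2b was lower with rosi in both B6 iWAT (58.9 to 9.15 CPM) and 129 iWAT (52.9 to 21.8 CPM), and its interaction was 1.40 ± 0.24 (adjusted p = 0.045).

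The 2 runs with the highest share of reads in no gene feature, 64.3 to 67.7% and 66.8 to 70.6%, held the first set of B6 eWAT and the F1 libraries, while the other 5 ran from 29.3 to 49.1%. Comparisons within those groups lay in 1 run each. Levels in F1 were not tested against those in B6 or 129, since strain and run differ together, and the overlaps and correlations of the rosi effect in F1 with that in B6 or 129 set effects found within 1 run side by side.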
